A study of Homo sapiens with 6 samples.

How the data were processed

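The series measured trimethylation of histone H3 at lysine 4 (H3K4me3) by chromatin immunoprecipitation and sequencing (ChIP-seq) in T47D cells, an established luminal breast cancer line. Per the labels' protocols, cells received medium with MK2206, an allosteric inhibitor of the AKT kinases, or with the solvent DMSO. Chromatin was crosslinked and sonicated, precipitated with an Abcam H3K4me3 antibody, and made into libraries with a ThruPLEX-FD kit. There were 6 libraries, 3 per treatment. The titles of the 3 libraries of each treatment end in 24, 48 and 72 with no unit, while the treatment protocol names 24 hours for all 6, so the numbers were used as names that the treatments share and not as times. Any effect of what the number marks is part of the spread between libraries. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

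The authors deposited 1 list of peaks per library, with a chromosome, start, end, peak name and score for each peak and no header. FastQC 0.10.0, Bowtie 0.12.7, MACS2 2.0 and the human genome build hg19 are named in the submitters' processing notes, without their role or order. The use of an input control, the calling threshold and any filters are not given in the sources used here. The score is the authors' own value per peak in the deposited lists. Its scale is not given in the sources used here, and it served only to rank or filter peaks within a list. No peaks overlapped within a list, and the narrowest peak had 200 bp in each of the 6 lists. The lists hold no read counts, so the depth of each library is unknown. How many weak peaks a list holds depends on depth and on the efficiency of the precipitation as well as on the histone mark. Intervals on shares of peaks cover counting error only, and neighbouring peaks are not independent.

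Peak names differed between libraries. Both lists numbered 72 used another naming style than the other 4, and the smallest gap between neighbouring peaks was 51 bp in these lists and 77 bp in the other 4. The names in the MK2206 list numbered 24 lack a letter that the names of the other 3 lists of their style carry. The lists numbered 72, and that MK2206 list, may thus have been processed apart. Each treatment has 1 list numbered 72, so results are given per number, and counts were repeated without both.

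Values per library were the number of peaks, the base pairs covered, the median peak width, and the number of wide stretches, meaning stretches of at least 4 kb after joining peaks of a list within 1 kb of each other. Peak number, covered length and median width were compared on the log2 scale, and wide stretches as counts, with two-sided exact permutation tests over the 3 against 3 libraries, which cannot give a p below 0.10. Similarity of lists was the base-pair Jaccard index, the shared divided by the combined covered length. Consensus regions were the union of all 6 lists with overlapping or adjoining peaks merged, and a region was present in a library with at least 1 bp of overlap. A region was called lost when present in 3 of 3 DMSO and 0 of 3 MK2206 lists, and gained in the opposite case. Regions were grouped by their mean covered length over all 6 libraries, with limits at 250, 500, 1000, 2000 and 4000 bp. Shares of peaks or regions have exact Clopper-Pearson 95% intervals.

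Covered base pairs per region were tested with limma (lmFit and eBayes with a trend) on log2(bp + 100) in the regions present in at least 3 of 6 libraries, after centring each library on its median over these regions, with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes are therefore relative to the median region, and differences on this scale understate changes of narrow regions. On simulated data with 200 changed regions among 35296, this test recovered 12% of changes of 0.5 and 43% of changes of 1 on the log2 scale, with 5 false calls among 60. It made 0 calls when no region was changed. The simulation drew independent noise around the mean of each region. It held no shift common to a treatment and no built-in absence from a treatment, so these rates may not hold for the real lists. Tools were bedtools 2.31.1, R 4.3.3 with limma 3.58.1, and Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

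Tests, alternatives and the rule for named regions were set before the data were examined. The rule takes 5 lost and 5 gained regions with the highest mean score percentile within the 3 lists that hold them. It also takes 5 narrower and 5 wider regions with the largest log2 difference among those under an adjusted p of 0.05 that moved the same way in all 3 number-matched comparisons. The widest regions were chosen after their values were seen, as were the grouping by covered length and the account by chromosome. Alternatives were leaving out each library, the higher-scoring 50% of each list, lists shortened to the same number of top-scoring peaks (32809), other overlap, joining and width limits, other centring, pseudocount and filters, and the title number as a block. Another 3 were added after the data were seen, namely leaving out both libraries numbered 72, the same number of joined stretches per list, and the same covered length per list.

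No hg19 gene annotation was used here. Positions are hg19 coordinates counted from 1, and no region is assigned to a gene, exon or promoter. The planned counts of marked, lost and gained promoters, the share of peaks near transcription start sites, and the tests of gene lists, including the cell type markers, need such an annotation and were not run. For the same reason width was tested per consensus region and not around transcription start sites.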

Results

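H3K4me3, a histone mark of active and poised promoters, was profiled in T47D breast cancer cells treated with the AKT inhibitor MK2206 or with DMSO, and the comparison asks how the mark differs after AKT inhibition. The 6 peak lists, 3 per treatment, are named by treatment and by the number 24, 48 or 72 in their titles. The DMSO lists held 43852, 38575 and 45546 peaks in this order of numbers, and the MK2206 lists 33108, 32809 and 39613. Read depth is unknown for all of them. The union of the 6 lists gave 51429 consensus regions, of which 23957 (46.6%) were present in all 6 and 10803 in 1 list only.

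Lists from MK2206-treated cells held fewer H3K4me3 peaks and covered less of the genome at each of the 3 numbers. DMSO libraries had 42658 ± 3636 peaks and MK2206 libraries 35177 ± 3845 (SD, n = 3 each), a ratio of geometric means of 0.824. The difference was -24.5% at number 24, -14.9% at 48 and -13.0% at 72. Covered length was 48.8 ± 2.46 Mb with DMSO and 41.6 ± 3.43 Mb with MK2206 (SD, n = 3 each), with differences of -20.4%, -14.7% and -9.08% at the same numbers. Without the MK2206 library numbered 24, whose peak names lack a letter found in the other lists of their style, the log2 difference was -0.24 for peaks and -0.21 for covered length, against -0.28 and -0.23 with all libraries. All 3 MK2206 lists covered less than any DMSO list, which gives the smallest p this design allows (two-sided exact permutation p = 0.1). For peak number, the MK2206 list numbered 72 exceeded the DMSO list numbered 48 (exact permutation p = 0.2). Median peak width was 688 ± 42.5 bp with DMSO and 745 ± 58.2 bp with MK2206 (exact permutation p = 0.3, n = 3 each). That direction turned when every list was shortened to its 32809 top-scoring peaks, with a log2 difference of -0.23 in place of 0.11.

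**Figure D1:**
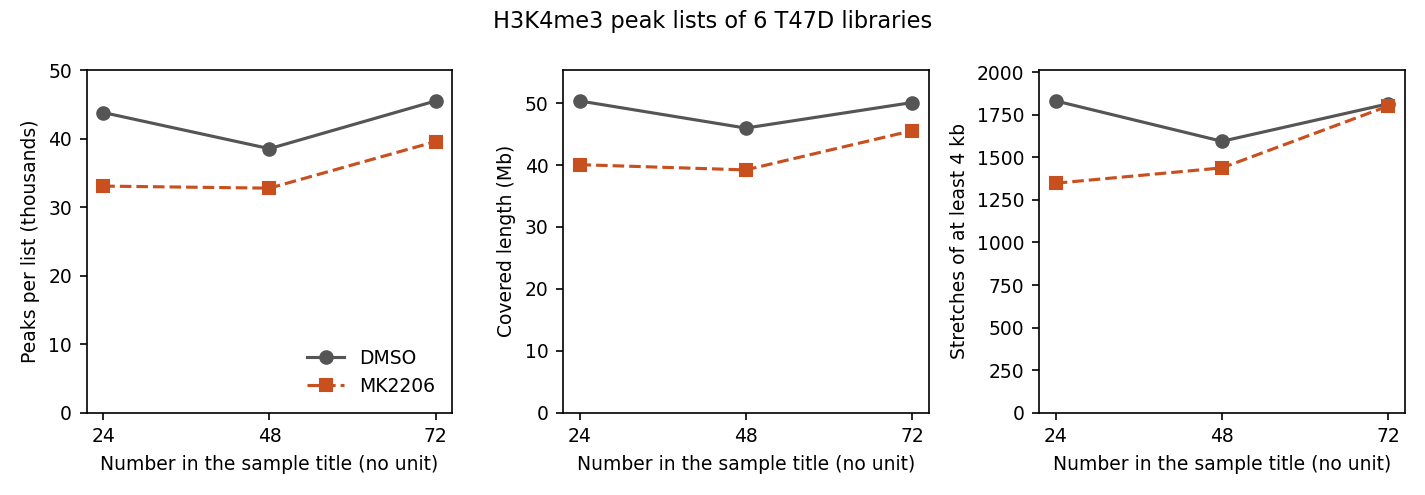
Peaks per list (in units of 1000), covered length (Mb) and stretches of at least 4 kb (number) for the 3 DMSO (grey circles) and 3 MK2206 (orange squares) libraries, against the number in the sample title, which has no unit. Lines only join libraries of a treatment. At each number the MK2206 library lies below the DMSO library in all 3 panels, by 13 stretches at 72 in the right panel.

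On average, libraries of the same treatment shared more of their covered bases than libraries of different treatments. The mean Jaccard index was 0.789 within treatments and 0.752 between them, a difference of 0.036 (exact permutation over the 10 splits of the libraries, p = 0.1, the smallest possible). The lists closest to each other were the MK2206 lists numbered 24 and 48, at 0.824, followed by the DMSO lists with these numbers, at 0.820. The DMSO list numbered 48 also overlapped the MK2206 list numbered 24 at 0.798. The MK2206 list numbered 72 was closer to the DMSO list numbered 72, at 0.772, than to the other MK2206 lists, at 0.762 and 0.758. Grouping the lists numbered 24 and 48 against those numbered 72, which have another style of peak names, gave 0.782 within and 0.754 between, a difference of 0.028. Setting the DMSO lists numbered 24 and 72 and the MK2206 list numbered 72 against the remaining lists also gave a difference of 0.028. Leaving out 1 library gave differences between treatments from 0.025 without the DMSO library numbered 24 (exact permutation p = 0.3) to 0.055 without the MK2206 library numbered 72 (exact permutation p = 0.1).

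The MK2206 peaks were largely a subset of the DMSO peaks. At number 24, 97.3% (95% interval 97.1 to 97.5) of MK2206 peaks overlapped a DMSO peak, while 68.8% (68.3 to 69.2) of DMSO peaks overlapped an MK2206 peak. The shares were 94.2% (93.9 to 94.5) and 73.5% (73.1 to 73.9) at number 48, and 90.5% (90.2 to 90.7) and 75.2% (74.8 to 75.6) at number 72. There was 1 library per treatment at each number, so these shares have no replicate check at a single number. Lists of equal length bring these shares together by construction. With 32809 top-scoring peaks in every list, 92.1%, 90.8% and 88.7% of MK2206 peaks overlapped a DMSO peak at numbers 24, 48 and 72, against 85.6%, 82.4% and 84.7% of DMSO peaks.

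The missing regions were mostly narrow by their mean covered length. Of DMSO regions with a mean covered length under 250 bp over all 6 libraries, 86.7%, 87.5% and 71.7% were absent from the MK2206 list with the same number (24, 48 and 72). Among regions of 250 to 500 bp the shares were 30.8%, 39.8% and 17.1%, and among those of 500 to 1000 bp they were 3.33%, 6.93% and 1.62%. Between 1000 and 2000 bp they were at most 0.207%. All 6819 regions of 2000 to 4000 bp and all 1220 of at least 4000 bp were present in all 6 lists. Narrow regions also went missing in the other direction. Of MK2206 regions under 250 bp, 27.6%, 58.4% and 46.7% were absent from the DMSO list with the same number. The grouping uses the mean over the same 6 libraries, so a region absent from several lists falls into a narrower class by construction.

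Regions present in all 6 lists were covered over slightly fewer bases with MK2206. The median log2 ratio of covered length was -0.17, -0.13 and -0.04 at numbers 24, 48 and 72, a mean of -0.11 ± 0.07 (SD, n = 3 numbers). For regions of 500 to 1000 bp the medians were -0.31, -0.30 and -0.15. For regions of at least 4000 bp they were -0.07, -0.03 and 0.0051, with 80.0%, 61.8% and 47.5% of these regions narrower with MK2206.

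**Figure D2:**
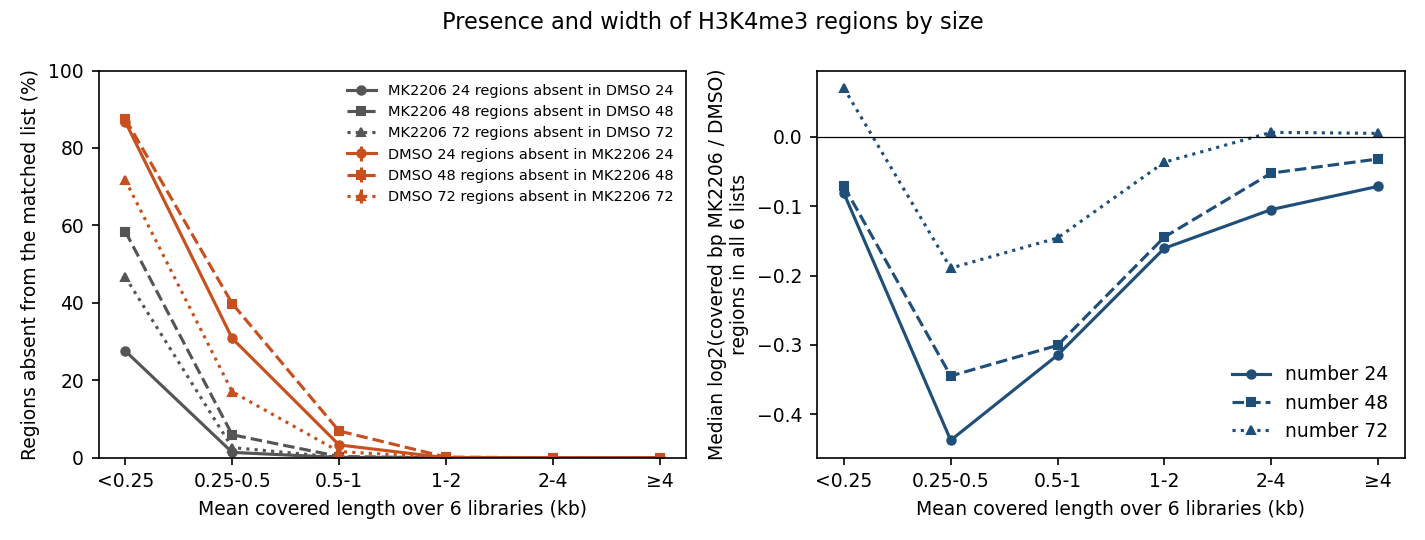
Left, share of regions (%) of a list absent from the list of the other treatment with the same number, by mean covered length over the 6 libraries (kb), for DMSO regions (orange, absent with MK2206, with 95% intervals that are mostly smaller than the symbols) and MK2206 regions (grey, absent with DMSO). Right, median log2 ratio of covered length, MK2206 over DMSO, in regions present in all 6 lists, by number. Absence reaches 87.5% under 250 bp and 0 from 2000 bp upwards, and the class under 250 bp in the right panel holds 10 regions.

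Across all libraries, 1541 regions were present in 3 of 3 DMSO and 0 of 3 MK2206 lists, which is 4.94% of the 31223 regions present in 3 of 3 DMSO lists. The opposite held for 22 regions, 0.0903% of the 24370 present in 3 of 3 MK2206 lists. Lost regions had a median width of 526 bp and gained regions of 617 bp, against 1657 bp for regions in all 6 lists. The widest lost region had 2160 bp, and 60 had at least 1 kb. Lost regions lay low in the DMSO score rankings, at median percentiles of 22.8, 17.6 and 25.6 (numbers 24, 48 and 72), where regions in all 6 lists lay at 71.97, 68.3 and 72.9.

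By the authors' scores, the highest-ranked lost region lay on chromosome 20 (47237134 to 47237679, hg19), at a mean percentile of 54.9. It had 383, 473 and 495 bp covered in the DMSO lists numbered 24, 48 and 72, and no peak with MK2206. A region on chromosome X (40215718 to 40216361) followed at percentile 49.0, with 505, 600 and 613 bp. The next were on chromosome 10 (21808998 to 21809619, 342, 276 and 622 bp), chromosome 11 (69913729 to 69914685, 834, 394 and 787 bp) and chromosome 4 (154360166 to 154360726, 491, 525 and 561 bp). The highest-ranked gained region, on chromosome 14 (31923487 to 31924695), lay at a mean percentile of 34.8 and had 360, 1209 and 1069 bp in the MK2206 lists numbered 24, 48 and 72. The other 4 named gained regions were on chromosome 21 (30813658 to 30814551, 200, 885 and 742 bp), chromosome 22 (43011378 to 43011911, 263, 332 and 534 bp), chromosome 3 (44383430 to 44384022, 301, 410 and 593 bp) and chromosome 4 (89200029 to 89201113, 912, 640 and 672 bp).

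The counts of lost and gained regions changed when the lists were made equal, and equal numbers of peaks or stretches draw both counts together by construction. With the same number of top-scoring peaks in every list, 453 regions were lost and 103 gained. With the same number of joined stretches the counts were 211 and 128, and with the same covered length in every list they turned to 2 lost and 657 gained. That last setting left lists of 19944 to 32809 peaks, so it did not equalise how many ranked peaks each list held. In it, the DMSO library numbered 48 and the MK2206 libraries numbered 24 and 48 together held 765 regions absent from the other 3, more than the 3 MK2206 libraries. In the higher-scoring 50% of each list they were 816 and 0, and merging peaks within 1 kb left 10 gained. Fewer required libraries raised the counts, to 4489 and 104 without both libraries numbered 72. Lost counts were 3367, 2521 and 3241 without the DMSO libraries numbered 48 or 72 or the MK2206 library numbered 72. Gained counts were 46 and 56 without the DMSO library numbered 24 or 72, and 127, 68 and 51 without the MK2206 library numbered 24, 48 or 72.

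**Figure D3:**
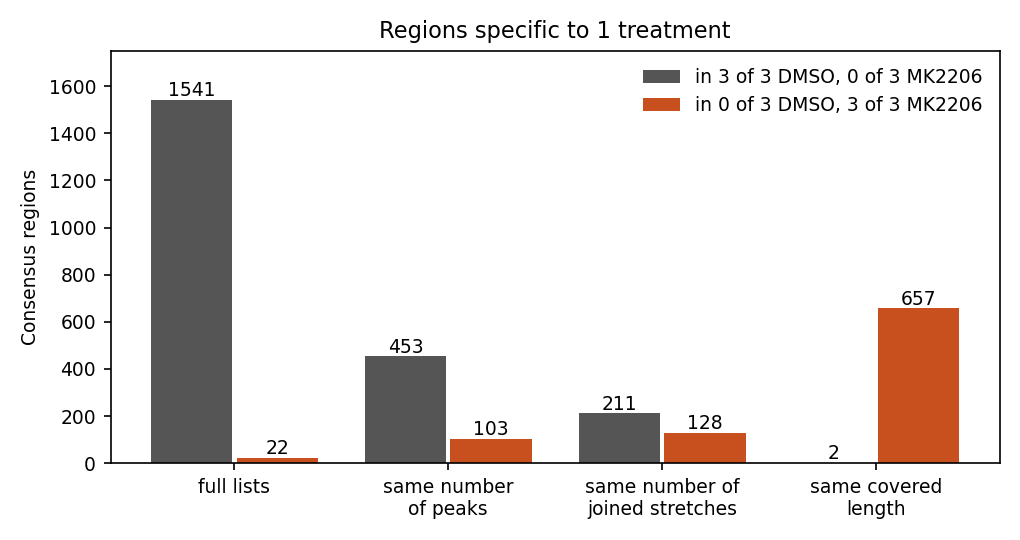
Number of consensus regions present in all 3 lists of 1 treatment and none of the other, for DMSO-specific (grey) and MK2206-specific (orange) regions. The full lists give 1541 and 22, and lists made equal in peaks, joined stretches or covered length give 453 and 103, 211 and 128, and 2 and 657. With equal covered length the lists differ in length, from 19944 to 32809 peaks, and a group of libraries from both treatments held 765 such regions. A peak below the cut of a shortened list counts as absent.

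In the limma test of covered length over 35296 regions, 1296 regions were narrower and 2878 wider with MK2206 at an adjusted p under 0.05, relative to a median shift of -0.30 on the log2 scale. Without centring the counts were 1936 narrower and 45 wider, and with quantile normalization 60 and 22, so the balance of directions changed with the scaling. With median centring as the method, the balance also turned, to 898 narrower and 272 wider in the higher-scoring 50% of each list. The counts were 651 and 11270 with no filter on presence and 383 and 876 with a pseudocount of 500 bp. Another list or filter also changes the regions whose median sets the centre, so the scaling was not the same in these fits. Of the narrower regions, 1062 were absent from all 3 MK2206 lists. Of the 2878 wider ones, 764 had a lower mean covered length with MK2206 than with DMSO and were wider only relative to the median. Of the wider ones, 2847 were present in all 6 lists, where the median shift was -0.15, and a fit to such regions alone gave 63 wider. All 1296 narrower regions and 644 of the 2878 wider ones moved in the named direction in all 3 number-matched comparisons.

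The 5 named narrower regions had no peak in any MK2206 list. They lay on chromosome 11 (70446083 to 70448132), with 1889, 1352 and 1442 bp in the DMSO lists numbered 24, 48 and 72, on chromosome 3 (58510424 to 58512583), with 2160, 1508 and 749 bp, and again on chromosome 11 (72938708 to 72940163), with 1270, 1121 and 1417 bp. The remaining 2 were on chromosome 11 (48107291 to 48108577, 1174, 1203 and 1097 bp) and chromosome 5 (148112114 to 148113316, 1140, 1143 and 1081 bp). Limma's adjusted p was 0.042 for each of the 5. Among the 5 named wider regions were the gained regions on chromosomes 14 and 4 given above and a gained region on chromosome 8 (96152167 to 96153610), with 230, 994 and 1037 bp in the MK2206 lists. A region on chromosome 9 (12797068 to 12799727) had 704, 1737 and 1877 bp with MK2206 and 0, 0 and 584 bp with DMSO (limma adjusted p = 0.045). A second region on chromosome 4 (108815264 to 108816741) had 954, 962 and 1360 bp with MK2206 and 0, 0 and 383 bp with DMSO (limma adjusted p = 0.042).

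The number of calls depended on which libraries entered the fit. No region passed limma's adjusted threshold without the DMSO library numbered 24 or 72 or the MK2206 library numbered 48, nor without both libraries numbered 72. At an unadjusted p under 0.05 these fits held 837 and 4616, 961 and 4928, 3027 and 6172, and 1522 and 6499 narrower and wider regions, in this order. There were 1 narrower and 1 wider without the DMSO library numbered 48, 3 and 2 without the MK2206 library numbered 24, and 3912 and 6790 without the MK2206 library numbered 72. With 32809 peaks in every list 6 regions were narrower and 8 wider, and among regions present in all 6 lists 67 and 63.

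Wide H3K4me3 stretches, which in many cell types lie at genes of cell identity, numbered 1746 ± 132 with DMSO and 1529 ± 240 with MK2206 (SD, n = 3 each) at a limit of 4 kb. The difference of -217 was within the spread between libraries (two-sided exact permutation p = 0.2). It was -483 at number 24, -156 at 48 and -13 at 72. With 32809 peaks in every list the difference was -110.3 (exact permutation p = 0.5). Without the MK2206 library numbered 24 it was -127, and without that numbered 72 it was -353.

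The widest regions differed little between treatments. The widest, on chromosome 3 (18457537 to 18489704), was covered over 30.8 ± 0.027 kb with DMSO and 31.4 ± 0.10 kb with MK2206 (SD, n = 3 each), a difference of 2.08%. Next came regions on chromosome 8 (116655949 to 116685282), with 28.5 ± 0.14 and 28.9 ± 0.33 kb, and chromosome 10 (8086745 to 8114811), with 27.4 ± 0.12 and 27.2 ± 0.59 kb. The region on chromosome 12 at 116691122 to 116716776 had 25.1 ± 0.12 kb with DMSO and 24.0 ± 0.41 kb with MK2206, and that on chromosome 2 (11679210 to 11701485) 21.8 ± 0.33 and 20.6 ± 0.64 kb. Of the 10 widest, the region on chromosome 14 (38051616 to 38070463) differed most, with 18.2 ± 0.16 kb against 16.2 ± 0.67 kb, a difference of -11.1%. A region on chromosome 9 (12771577 to 12788893) went the other way, with 15.5 ± 0.23 kb against 16.5 ± 0.44 kb, or 6.14%. In all of these regions except that on chromosome 10 the libraries of the treatments did not overlap (exact permutation p = 0.1 each, unadjusted, n = 3 per treatment). They did overlap in the regions ranked 6, 8 and 9 by width, on chromosomes 12 (54373817 to 54395351), 15 (96867561 to 96885052) and 6 (10404787 to 10421306). None of these regions passed limma's adjusted threshold, which does not show that they were unchanged. For the widest region limma's SE was 0.34, beside a log2 difference in covered length of 0.030. Limma compares each region with the median region, and on that scale the region on chromosome 14 had a log2 difference of 0.13 (SE 0.17, adjusted p = 0.65), opposite in sign to its difference in covered length, while that on chromosome 9 had 0.38 (SE 0.16, adjusted p = 0.14).

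**Figure D4:**
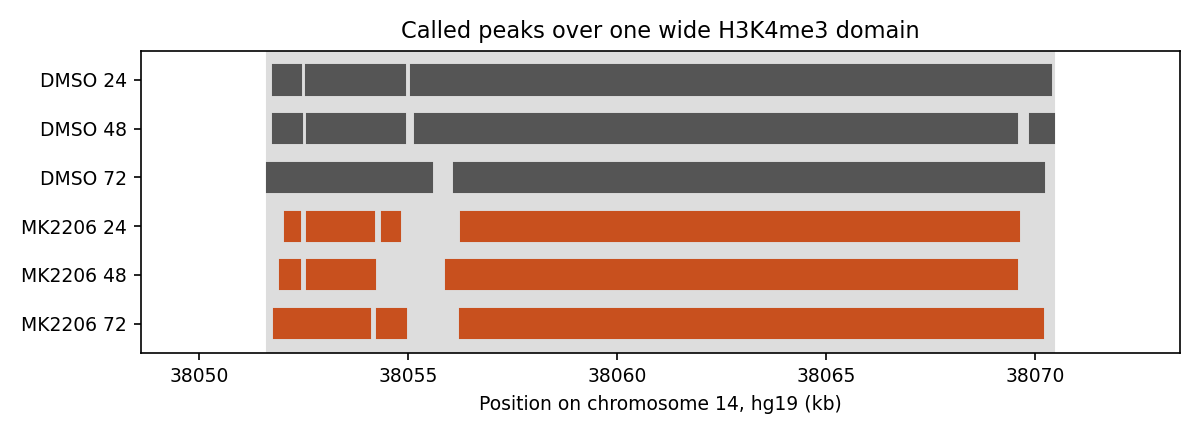
Called peaks (bars) of the 3 DMSO (grey) and 3 MK2206 (orange) libraries along the wide region on chromosome 14, 38051616 to 38070463 (light grey), with hg19 position in kb on the horizontal axis. Covered length is 18354, 18068 and 18084 bp with DMSO and 15767, 15772 and 16924 bp with MK2206 at numbers 24, 48 and 72.

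Over the 1220 regions with a mean covered length of at least 4 kb, every MK2206 library lay below every DMSO library in 242 (19.8%) and above in 81 (6.64%), where chance gives 5% each way for 3 libraries against 3. The split that sets the DMSO libraries numbered 24 and 72 and the MK2206 library numbered 72 against the other 3 gave 255 and 7. Among the 20 widest regions the MK2206 libraries lay below in 7, above in 3, and overlapped the DMSO libraries in 10.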

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

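The covered length of some wide regions differed between treatments in 1 direction at numbers 24 and 48 and in the other at number 72. On chromosome 10 (8086745 to 8114811) the MK2206 library had -873 and -94 bp relative to DMSO at numbers 24 and 48, and 413 bp at 72. On chromosome 12 (54373817 to 54395351) the differences were -1046, -1204 and 229 bp. On chromosome 15 (96867561 to 96885052) they were 272, 249 and -483 bp. The median log2 ratio over regions present in all 6 lists turned in the same way in 3 size classes. It was -0.10, -0.05 and 0.0066 for regions of 2000 to 4000 bp, and -0.07, -0.03 and 0.0051 for regions of at least 4000 bp. It was -0.08, -0.07 and 0.070 for the 10 regions under 250 bp. With 1 library per treatment at each number, the difference between numbers was not tested. The libraries numbered 72 are also those with another style of peak names, and no biological explanation was tested.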

How the results depend on the processing

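Peak number, covered length, wide stretches and list similarity kept their direction under all alternatives run, and none of their tests could reach a p under 0.05 in this design. Median width turned to -0.23 with lists of equal length. Shortening removed low-scoring peaks from the longer lists and none from the MK2206 list numbered 48, which held 32809. How far this removal accounts for the turn was not tested. Shortened lists count a peak below the cut as absent. Lost and gained regions numbered 816 and 0 in the higher-scoring 50% of each list, and 453 and 103 in lists of equal length. Added after the data were seen, they were 211 and 128 with equal numbers of joined stretches, 2 and 657 with equal covered length (lists of 19944 to 32809 peaks), and 4489 and 104 without both libraries numbered 72. Merging within 1 kb gave 10 gained. Leaving out 1 library gave 1826 to 3367 lost and 25 to 127 gained, where fewer lists had to agree. Matched overlap of DMSO peaks (numbers 24, 48, 72) was 62.4%, 67.5% and 69.0% when 50% of a peak had to be covered, 73.7%, 80.3% and 82.8% in the higher-scoring 50%, and 85.6%, 82.4% and 84.7% with equal lengths. For MK2206 peaks it was 96.2%, 92.4% and 87.4%, then 99.96%, 99.7% and 97.9%, then 92.1%, 90.8% and 88.7%.

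Narrower and wider regions in limma numbered 1936 and 45 without centring, 60 and 22 with quantile normalization, 383 and 876 with a pseudocount of 500 bp, and 67 and 63 in regions covered in all 6 libraries. They were 651 and 11270 with no filter, 898 and 272 in the higher-scoring 50%, and 6 and 8 with equal lengths. Leaving out 1 library gave 0 to 3912 narrower and 0 to 6790 wider. Calls were 0 without both libraries numbered 72, where 1522 and 6499 passed an unadjusted p of 0.05. Unadjusted counts were 837 and 4616 without the DMSO library numbered 24, 961 and 4928 without that numbered 72, and 3027 and 6172 without the MK2206 library numbered 48. The cause was not tested. With all 6 libraries many regions shared the adjusted p of 0.042, close to the threshold. The title number as a replicate block gave 1629 and 6923. Deviations of same-numbered libraries correlated at 0.090, 0.19 and 0.42 across regions, so the numbers were not taken to pair the libraries. The DMSO library numbered 48 correlated nearly alike with the MK2206 libraries numbered 24 (0.20) and 48 (0.19). Those numbered 24 with DMSO and 48 with MK2206 correlated at 0.046. Between a library numbered 72 and one of another number the correlations were negative, from -0.34 to -0.12. Deviations within a treatment are tied to each other by construction. Paired exact sign-flip permutation tests of the 4 measures per library gave p = 0.25, the smallest that 3 pairs allow. Promoter, gene list and window alternatives were not run, since they need an hg19 gene annotation. Depth is unknown, so weak peaks missing from a list cannot be separated from peaks below its detection limit.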

Other observations

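The analyses here of chromosomes, of split regions and of regions beside shared ones, and the tests of list length, of the libraries numbered 72 and of gained regions across splits, were chosen only after the result was seen. Regions present in all 6 lists were more often broken into several peaks with MK2206. The share of these 23957 regions holding 2 or more peaks was 8.85%, 9.46% and 12.1% in the DMSO lists numbered 24, 48 and 72, and 13.5%, 16.5% and 16.1% in the MK2206 lists. The means were 10.1% ± 1.70 and 15.4% ± 1.62 (SD, n = 3 each), with a difference of 5.25 points (two-sided exact permutation p = 0.1, the smallest possible). The wide region on chromosome 14 at 38051616 to 38070463 shows such breaks in both treatments.

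Chromosomes differed in the share of DMSO regions missing with MK2206. Of chromosomes 1 to 22 and X, chromosome 19 had the lowest shares, 19.4%, 14.4% and 13.2% at numbers 24, 48 and 72, against 31.0%, 25.7% and 25.1% over the other chromosomes. Of its regions present in 3 of 3 DMSO lists, 2.18% were lost, against 7.42% on chromosome 13 and 6.38% on chromosome 18.

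Whether the excess of lost over gained regions came from how far down the ranking of peaks each list reaches stays open, since with the same number of joined stretches per list the ratio was 1.65 against 70.0 over the full lists, while the highest ratio of the other splits was 1.53 against 100.7, so the limit itself largely sets the balance. The excess did not rest on the libraries numbered 72 alone, since the ratio was 43.2 without both. Each treatment holds 1 of them, and the remaining DMSO lists were still longer than the remaining MK2206 lists. The ratio therefore cannot judge whether processing of the libraries numbered 72 contributed. The 10 splits of 3 against 3 are too few for a share under 0.05 (1 of 10 reached 1541 lost regions, the highest other being 1007 with the 3 longest lists on 1 side, and 1 of 10 reached limma's 4174 calls, the highest other being 0, with up to 2338 and 2519 regions at an unadjusted p under 0.05), and for gained regions 16 of the 20 sides held 22 or more, so chance is not excluded for these. A true loss of weak H3K4me3 sites after AKT inhibition would also shorten the lists and stays open, as do depth and the efficiency of precipitation.

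The low share missing on chromosome 19 could come from its widths or its score ranks. Regions of other chromosomes with the same covered length, in 10 classes, predicted 22.04%, 16.8% and 17.0% missing at numbers 24, 48 and 72. These predictions lay above the 95% intervals of the observed shares, with a largest difference of -3.84 points. The intervals cover counting error only and neighbouring peaks are not independent, so width alone is not excluded. Regions with the same score percentile, in 20 classes, predicted 18.8%, 14.1% and 14.4%, within the intervals (17.7 to 21.3, 12.8 to 16.2 and 11.7 to 14.8), with a largest difference of -1.25 points. A candidate explanation is therefore that chromosome 19 holds fewer low-scoring peaks, whatever sets their scores. Width and score were matched in unlike numbers of classes and not together, so they were not separated.

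Regions found with MK2206 but not DMSO lay more often beside shared regions. Of the 22 gained regions, 13 (59.1%) lay within 2 kb of a region present in all 6 lists, against 145 of 1541 lost regions (9.41%, two-sided Fisher's exact p = 1.6e-08 over regions, which are not independent). Of regions in 1 list only, 11.0%, 15.5% and 12.2% did so in the DMSO lists numbered 24, 48 and 72, and 19.8%, 29.7% and 24.6% in the MK2206 lists. Among regions held only by 3 libraries drawn from both treatments, the share within 2 kb ranged from 0% to 36.4% (4 of 11). Merging peaks within 1 kb left 10 gained and 1400 lost regions, so the gained count rests in part on the joining limit. List length also differed between the treatments and was not tested as a cause here. An effect of the treatment is a hypothesis that cannot be told apart from chance with 3 libraries each (12.9% ± 2.30 against 24.7% ± 4.99, SD, difference 11.8 points, exact permutation p = 0.1).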
